A study of Mus musculus with 20 samples.

How the data were processed

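Bulk RNA sequencing was used to measure 10 mouse tissues (ovary, uterus, liver, kidney, spleen, thymus, lung, heart, intestine and brain) in 20 libraries, 1 per tissue and treatment. The labels name the treatments DHEA and "sasame oil", and the second is called control here. The series text calls the libraries bulk, and the values are treated as such, although the sample descriptions also read "10x Genomics". The title and design text leave lung out. DHEA (dehydroepiandrosterone) is a steroid of the adrenal gland that tissues convert to androgens and oestrogens, and sesame oil is a usual carrier for it. Per the labels, the mice were wild type, each tissue was homogenised after dissection, and total RNA was extracted with a kit before Illumina library preparation. The dose, the length of treatment, the age and strain of the mice and the number of mice are not given in the sources used here, nor is it given which tissues shared an animal. The sampled part of brain, heart and intestine is not given either.

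The authors deposited 1 table of FPKM values, that is, fragment counts scaled to gene length and library size, with 1 column per library and 24826 rows named by gene symbol. Every gene in it is above 0 in at least 1 library. The submitters' processing notes name HISAT2 2.0.5 as the aligner's name and version, and the genome builds hg38 and mm39. The counting tool, the gene annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Values of near-identical genes can therefore hold each other's reads, and antisense partners cannot be told apart. Genomic coordinates were not used here, because the reference at hand is of another build. The authors also deposited a table of log2 fold values, DHEA over control, for 11372 genes in each tissue. Of these genes, 11315 were found once in the FPKM table, and all 11315 were above 0 in every library. In each tissue the authors' deposited table differed from the log2 ratio of the FPKM values by 1 constant, from -0.07 in kidney to 0.24 in uterus. That constant was close to the log2 ratio of the summed FPKM values, control over DHEA (0.238 for both in uterus, 0.229 for both in lung). The authors' table is thus close to ratios after scaling each library to the same FPKM sum.

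For 24808 of the 24826 genes (99.9%), the FPKM values of a gene across libraries were whole multiples of the value of 1 read, at a relative tolerance of 1e-11. This gave the reads behind each value. The libraries held 13206906 to 20710011 such reads, which were 98.1 to 99.5% of the denominators of the FPKM values. A gene of 2 kb at 5 FPKM rests on 134 to 209 reads. When the recovery was tested on simulated data, every count came back for 96.7% of 24618 simulated genes, and for 99.9% of those detected in 5 or more libraries.

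Within a tissue, genes were compared as the log2 ratio of DHEA to control after adding a pseudocount of 1 FPKM, on the FPKM values as deposited. Genes with a pair mean of at least 5 FPKM were counted as higher or lower when the ratio was at least 2-fold. Such ratios understate the difference of genes with low values. The 28 symbols that occur more than once (57 rows) were left out. With 1 library per group there is no replicate check, so no p-value is given within a tissue. Folds printed in the text are ratios of FPKM values, with an exact (Clopper-Pearson) 95% interval from the reads, which covers counting error only and not the variation between mice. Against a library with 0 reads, the fold was computed against a floor of 3 reads in that library and is written as "at least".

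Gene lists for pathways, cell types and signs of RNA quality, 68 in all with 1078 of their 1094 genes in the table, were fixed before the data were examined, as were the thresholds, the alternatives and the rule for naming genes. A list was read in a tissue when at least 5 members had a pair mean of 1 FPKM or more. Its median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is called apart at or under the percentile 2.5 or at or over 97.5, as a description of these libraries. In simulated data from heart (10316 genes), 3.5% of 200 random lists of 15 genes were called apart, and 100% of the same lists were called higher once raised by 0.5 on the log2 scale. Heart had the smallest spread of log2 ratios of the 10 tissues (SD 0.262, against 0.979 in uterus), so the 100% does not carry over to the others. The 3.5% applies to genes picked at random, not to genes that vary together. A list median is not a bound where members have 0 reads in a library. This applied to 15 of 484 combinations of list and tissue, and placing such members at their bound moved 1 median by over 0.1 and changed the sign of 0.

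Across tissues, a change shared by tissues was tested with limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), with tissue as a block, in 14833 genes with a mean of at least 1 FPKM. Benjamini-Hochberg adjusted p-values under 0.05 were called. These p-values measure the spread between tissues, and tissues of the same mouse are not independent. In data simulated with the same 14833 genes, log2(FPKM + 1) was shifted by a fixed amount in all tissues. The test called 30 of 50 genes shifted by 0.585, 45 of 50 by 1, 49 of 50 by 2 and 42 of 50 by -1, with 2 false calls. Where a gene is near 0 FPKM in a tissue, such a shift exceeds the same fold of FPKM. A real change of that fold could therefore be called less often. Signs were flipped for each gene and tissue separately, so the 2 false calls do not cover genes that vary together. All shifts were applied at once, and the resulting 168 calls ease the adjusted threshold. Where few genes change, a smaller share of them would pass. Gene lists with a median in all 10 tissues were tested with an exact two-sided sign-flip permutation test over 1024 sign assignments, with Benjamini-Hochberg adjustment over lists.

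The named genes are the 10 with the largest positive and negative log2 ratios in ovary and uterus, the 5 largest in each other tissue, and up to 4 members with the largest absolute ratio in each list described. Esr1, Cyp17a1 and Kap were named in ovary, uterus, kidney and liver in any case. Some genes that this rule picked are not reported. Across tissues the 5 smallest p-values in each direction were named. Predicted genes, pseudogenes and segments of antigen receptors were skipped. Alternatives were another pseudocount, other filters, a 4-fold threshold, centring on the tissue median, rescaling the libraries without mitochondrial and the 20 most abundant genes, the authors' deposited log2 table, list means, other forms of the limma fit, and leaving out tissues. A fit by limma-voom on the recovered reads and a fit without brain, intestine and heart were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.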

Results

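The series holds 20 bulk RNA-seq libraries from 10 tissues of wild-type mice, 1 control and 1 DHEA library in each tissue. Mice given DHEA in oil are used as a model of androgen excess, and the comparison asks which transcripts differ between treated and control animals in reproductive, metabolic, immune and other organs. The libraries held between 13206906 reads (intestine, DHEA) and 20710011 reads (brain, control). Marker lists of the 10 tissues were each highest in the 2 libraries of their own tissue, in 10 of 10 tissues. No tissue has a replicate, so each ratio below describes a pair of libraries.

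The uterus pair differed in 625 genes 2-fold higher and 803 genes 2-fold lower in the DHEA library, among 7965 genes at 5 FPKM or more. Intestine followed with 680 higher and 209 lower of 6189 genes, brain with 408 higher and 431 lower of 7596, and spleen with 452 higher and 74 lower of 7882. Ovary had 169 higher and 225 lower genes of 8549, and liver 80 higher and 112 lower of 4850. Smaller counts were found in thymus (91 higher, 11 lower, of 7727), kidney (78 higher, 36 lower, of 6985), lung (63 higher, 69 lower, of 7913) and heart (27 higher, 19 lower, of 5620). The split between higher and lower genes depended on scaling in several tissues. Rescaling without mitochondrial and the most abundant genes turned the larger side in uterus (744 higher and 672 lower), lung (80 and 50), heart (24 and 25) and brain (425 and 416), and centring on the tissue median turned it in uterus (727 and 655) and brain (440 and 385). This rescaling moved the log2 ratios by 0.12 in uterus and -0.11 in heart, and the median ratio as deposited was -0.12 in uterus and 0.11 in intestine. The authors' deposited table gave 742 higher and 498 lower genes in uterus, 33 and 29 in kidney, 114 and 17 in lung, and 753 and 81 in intestine. It differs in its constants, in its smaller set of genes and in having no pseudocount, so these counts do not show scaling alone. Centring gave 87 higher and 27 lower genes in kidney and 570 and 263 in intestine. Of 484 combinations of list and tissue, 213 (44.0%) stood apart from random lists, 102 higher and 111 lower, so standing apart is common in these libraries.

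**Figure D1:**
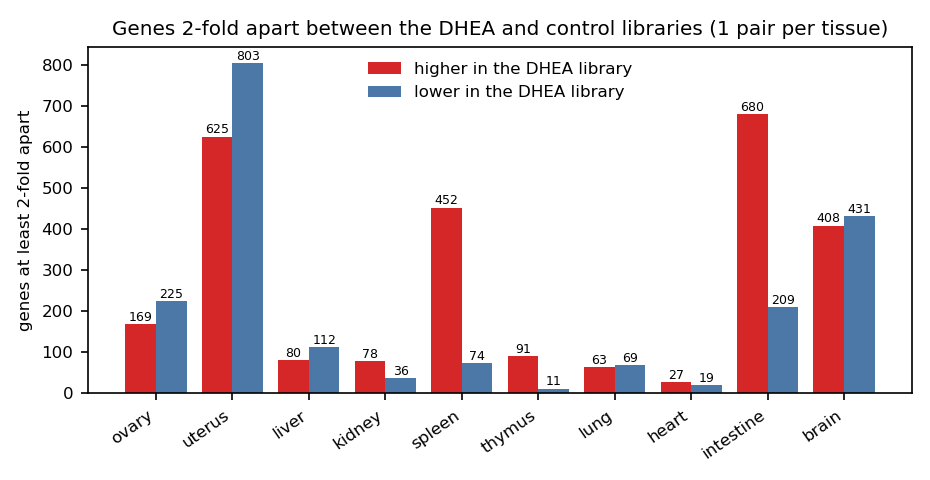
Number of genes at least 2-fold higher (red) or lower (blue) in the DHEA library than in the control library of the same tissue, among genes with a pair mean of at least 5 FPKM. Uterus has 625 higher and 803 lower genes and heart has 27 and 19, with 1 library per tissue and treatment.

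In the ovary, transcripts of ovulation and corpus luteum and of steroid synthesis were lower in the DHEA library, and several granulosa cell transcripts were higher. The oestrous stage of the mice is not given in the sources used here and cannot be told apart from DHEA in this pair. Edn2, an endothelin made by granulosa cells around ovulation, was at 92.4 FPKM in control and 0.273 in DHEA, 338-fold lower (95% counting interval 155 to 922). Akr1c18, which inactivates progesterone, was 14.3-fold lower (13.1 to 15.7; 425 against 29.6 FPKM). Cyp19a1, the aromatase that makes oestrogens from androgens, was 6.53-fold higher (5.88 to 7.27; 4.95 against 32.4 FPKM), and Fshr, the receptor for follicle-stimulating hormone, was 4.69-fold higher (4.17 to 5.28). Spon1, an extracellular matrix protein, had 2.67 FPKM in control and 42.7 in DHEA (16.0-fold, 14.6 to 17.5), and Penk, the precursor of enkephalins, had 11.5 and 101 FPKM (8.82-fold, 7.88 to 9.89).

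Of 13 ovulation and corpus luteum genes measured in the ovary, 9 were 2-fold lower, 0 higher and 4 between, with a median log2 ratio of -1.43, apart from random lists. Sfrp4, a secreted Wnt inhibitor, was at 729 and 62.2 FPKM. The steroidogenesis list was also lower (6 of 17 members lower, 1 higher, median -0.52). Star, which carries cholesterol into mitochondria, was 13.03-fold lower (12.1 to 14.0; 171 against 13.1 FPKM), and Cyp11a1, which cleaves the cholesterol side chain, was 6.85-fold lower (6.73 to 6.98; 1256 against 183 FPKM). Cholesterol synthesis genes had 10 of 23 members 2-fold lower and 0 higher (median -0.76), such as Hmgcs1 at 96.7 and 28.5 FPKM. The largest shift of a long list was that of the immediate early genes, with 16 of 24 members lower and 0 higher (median -1.74), among them Arc (14.4 against 0.283 FPKM) and Egr3 (17.4 against 1.15 FPKM). Unfolded protein response genes were lower in 6 of 18 cases (median -0.66), and Ddit3 was at 56.2 and 11.3 FPKM.

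Granulosa cell markers stood apart on the higher side, with 3 of 16 members 2-fold higher and 0 lower (median 0.44). Inhba, an inhibin and activin subunit, was at 88.3 and 208 FPKM. Oocyte markers, with all 18 members between the 2-fold limits (median 0.38), and smooth muscle markers, with 1 of 12 members higher and 0 lower (median 0.59), were also apart on the higher side. Theca and interstitial cell markers were not apart (median -0.11, percentile 8.76), with 3 of 12 members 2-fold lower, 0 higher and a mean of -0.57. The other genes with the largest positive ratios were Rgs13, Asb4, Klk1, Dpep1, Mro, Gpnmb and Mir143, the last with 1 read in control and 9 in DHEA. Those with the largest negative ratios included Plekhg4, Sema3d (60.0 against 2.75 FPKM), Podnl1, S100g, Nrcam, Tnfrsf9 and Timp1 (307 against 23.6 FPKM). The oestrogen receptor gene Esr1 was at 4.02 and 3.49 FPKM, and Cyp17a1, the androgen-making enzyme of theca cells, at 7.26 and 9.72. Kap had 1 read in control and 0 in DHEA.

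**Figure D2:**
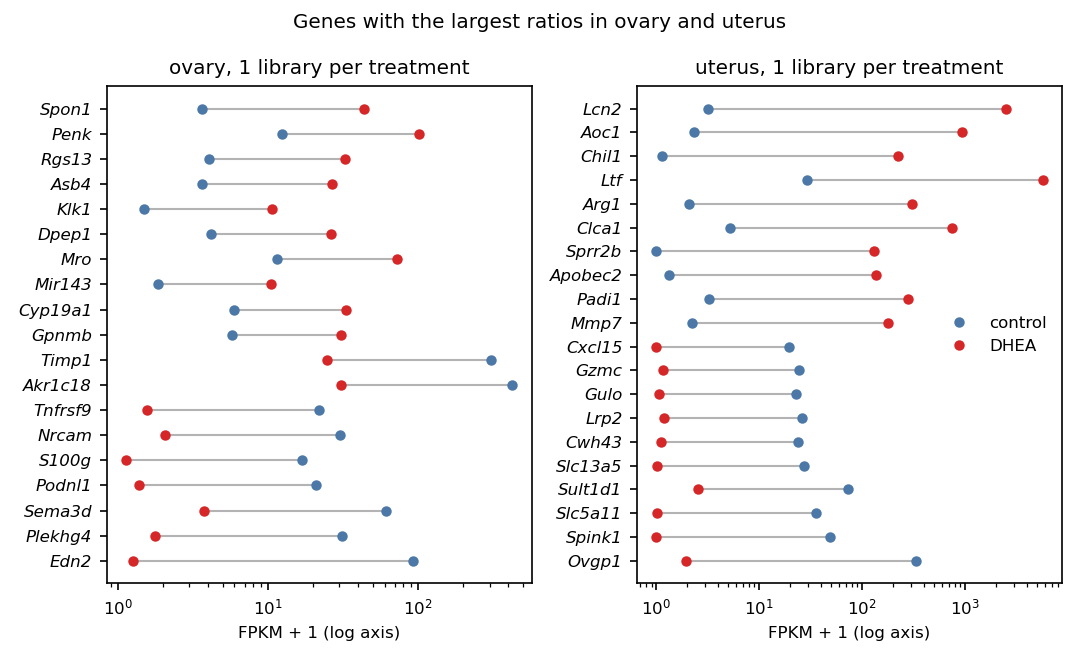
FPKM + 1 on a log axis of genes among the 10 largest positive and the 10 largest negative log2 ratios in ovary (left) and uterus (right), with the control library in blue and the DHEA library in red. In ovary Edn2 has 92.4 FPKM in control and 0.273 in DHEA, and in uterus Ltf has 28.0 and 5732 FPKM.

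In the uterus, secretory transcripts known to respond to oestrogen were far higher in the DHEA library. Ltf, the iron-binding lactoferrin, was at 28.0 FPKM in control and 5732 in DHEA (205-fold, 195 to 215), where it took 1.99% of all reads. Lcn2, an iron carrier of the innate defence, was at 2.16 and 2505 FPKM (1158-fold, 943 to 1438). Sprr2b, a cornified envelope protein, had 0 reads in control and 131 FPKM in DHEA, at least 550-fold higher. Ovgp1, a secreted glycoprotein typical of the oviduct, was 350-fold lower (276 to 450; 331 against 0.947 FPKM), and Spink1, a trypsin inhibitor, was at least 237-fold lower (47.6 FPKM against 0 reads).

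The oestrogen response list had 16 of 20 members 2-fold higher, 1 lower and 3 between (median 2.62, apart). Padi1, an enzyme that converts arginine to citrulline, was at 2.23 and 278 FPKM. The progesterone response list went the other way, with 10 of 14 members lower and 2 higher (median -1.25, apart). It includes Lrp2, an endocytic receptor (24.9 against 0.199 FPKM), Cyp26a1, which degrades retinoic acid (23.8 against 0.567 FPKM), and Ihh, the hedgehog ligand of the epithelium, at least 209-fold lower (10.0 FPKM against 0 reads). Uterine epithelium markers had 6 of 13 members lower and 1 higher (median -0.90). Esr1 was at 46.3 and 42.1 FPKM. Cyp17a1 had 3 reads in control and 0 in DHEA, and Kap had 1 and 4 reads.

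Matrix, cell cycle and macrophage lists were higher in the DHEA uterus, and T and NK cell and endothelial lists were lower. Extracellular matrix genes had 14 of 20 members 2-fold higher and 0 lower (median 1.41), with Col6a3, a collagen VI chain, at 22.7 and 310 FPKM. Cell cycle genes had 14 of 29 members higher and 0 lower (median 0.98), with the replication licensing gene Mcm5 at 4.51 and 20.8 FPKM. Macrophage markers had 9 of 12 members higher and 0 lower (median 1.60), and Adgre1, which encodes the F4/80 antigen, was 6.44-fold higher (5.76 to 7.23). Smooth muscle markers had 6 of 12 members higher and 0 lower (median 1.01), with Actg2 at 198 and 1265 FPKM. T and NK cell markers had 4 of 10 members lower and 0 higher (median -0.88), with the granzyme gene Gzmb at 15.02 and 0.612 FPKM, and thymocyte markers had a median of -0.74. Endothelium markers had 9 of 16 members lower and 0 higher (median -1.17), with Cldn5, a tight junction protein, at 52.0 and 10.6 FPKM. Cholesterol synthesis genes had 11 of 22 members higher and 1 lower (median 1.01), with Sqle, which oxidises squalene, at 2.03 and 13.3 FPKM. The remaining genes with the largest positive ratios were Aoc1, the histamine-degrading diamine oxidase (1.30 against 948 FPKM), Chil1, Arg1, Clca1, Apobec2 and Mmp7. The largest negative ratios included Slc5a11, Sult1d1, Slc13a5, Cwh43, Gulo, Gzmc and Cxcl15 (at least 268-fold lower).

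Other cell types and signs of RNA make-up differed between the same uterus libraries. Adipocyte markers had 13 of 15 members lower and 0 higher (median -2.41), with Adipoq, a hormone of fat cells, at 175 and 24.1 FPKM. The airway epithelium list, whose measured members include the ciliated cell genes Foxj1 (7.63 against 0.168 FPKM) and Dynlrb2, had 5 of 7 members lower and 1 higher (median -2.53). Mitochondrially encoded genes were lower in 13 of 13 cases (median -2.16) and took 5.79% of the reads in control and 1.45% in DHEA. Ribosomal protein genes were lower in 33 of 40 cases (median -1.24). The uterus pair had the lowest correlation across genes of the 10 pairs (Pearson r = 0.744 on the log2 scale), where genes are not independent replicates.

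In the liver, transcripts with known sex bias differed in the male direction. Mup7, a major urinary protein, was at 3.02 FPKM in control and 413 in DHEA (137-fold, 106 to 180), and Elovl3, a fatty acid elongase, at 0.342 and 24.8 FPKM (72.6-fold, 42.2 to 137). Sult2a2, a sulfotransferase that acts on steroids including DHEA, was at 480 FPKM in control and 0 reads in DHEA, at least 1849-fold lower. Its neighbour in sequence Sult2a1 had 4241 reads in control and 1 in DHEA.

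Of 13 male-biased liver genes measured, 9 were 2-fold higher and 0 lower (median 1.77, apart), with Hsd3b5 at 0.771 and 35.3 FPKM and Cyp2d9 at 17.3 and 203 FPKM. Of 23 female-biased genes, 17 were lower and 1 higher (median -1.77, apart), with A1bg at 104 and 2.67 FPKM and Cyp3a41a at 68.5 and 1.34 FPKM. Cholesterol synthesis genes had 11 of 24 members lower and 0 higher (median -0.94), such as Idi1 at 23.3 and 5.87 FPKM. PPAR-alpha targets stood apart on the higher side with 4 of 33 members higher and 1 lower (median 0.38), and Cyp4a14, a fatty acid hydroxylase, was at 221 and 1065 FPKM. Targets of the xenobiotic receptors CAR and PXR were not apart (median -0.02, percentile 49.1), nor were hepatocyte markers (median 0.08, percentile 90.0). Endothelium markers (2 of 13 members higher, 0 lower, median 0.77) and erythroid markers (3 of 7 higher, 1 lower, median 0.64) were apart on the higher side, and class II antigen presentation genes (6 of 6 between the limits, median -0.64) and mitochondrially encoded genes (3 of 13 lower, 0 higher, median -0.60) on the lower side. Single genes outside these shifts included Cyp7a1, the rate-limiting enzyme of bile acid synthesis (70.1 against 11.5 FPKM), Igfbp1, which binds insulin-like growth factors (9.84 against 90.7 FPKM), and Mt1, a metallothionein (390 against 38.4 FPKM). Mup14 and Mup15 were 61.0-fold and 34.3-fold higher. Esr1 was at 5.67 and 2.97 FPKM and Cyp17a1 at 100.4 and 81.7 FPKM, while Kap had 8 reads in control and 0 in DHEA (at least 2.16-fold lower). The Mup, Sult2a and Cyp3a genes belong to families of near-identical copies, and values of single members are uncertain.

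In the kidney, androgen-responsive transcripts of the proximal tubule were higher in the DHEA library. Cyp7b1, which hydroxylates oxysterols and DHEA, was at 1.20 FPKM in control and 170 in DHEA (142-fold, 107 to 194), and Slc7a13, an amino acid transporter, at 1.65 and 156 FPKM (94.1-fold, 73.6 to 122). Acsm3, an acyl-CoA synthetase, was at 0.258 and 68.3 FPKM (265-fold, 177 to 419). Kap, the kidney androgen-regulated protein, was already at 11942 FPKM in control and reached 24559 in DHEA (2.06-fold, 2.04 to 2.07). Scd1, the stearoyl-CoA desaturase, was 9.15-fold lower (8.84 to 9.47; 429 against 46.9 FPKM).

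The androgen-responsive kidney list had 9 of 13 members 2-fold higher and 0 lower (median 2.79, apart), and the female-biased kidney list had 4 of 8 members lower and 0 higher (median -0.82, apart). Gsta4 was at 142 and 39.8 FPKM, and Prlr, the prolactin receptor, at 16.9 and 5.86 FPKM. Genes of DHEA and androgen metabolism had 5 of 16 members higher and 0 lower (median 0.50), with Akr1c14, a hydroxysteroid dehydrogenase, at 5.44 and 69.6 FPKM. Cyp2j13 and Ugt2b37 completed the 5 largest positive ratios, and Ugt1a2 (238 against 9.69 FPKM), Ugt1a10, Abcc3 and Cbr1 the negative ones. Ugt1a genes share their last exons, so their values are uncertain. Renal tubule markers were not apart (median -0.13, percentile 3.22), and podocyte markers had a median of 0.03 (percentile 93.8). Adipocyte markers (4 of 12 members higher, 1 lower, median 0.42) and plasma cell markers (3 of 6 higher, 0 lower, median 0.77) were apart on the higher side. Esr1 was at 0.999 and 1.10 FPKM, and Cyp17a1 had 11 and 5 reads.

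**Figure D3:**
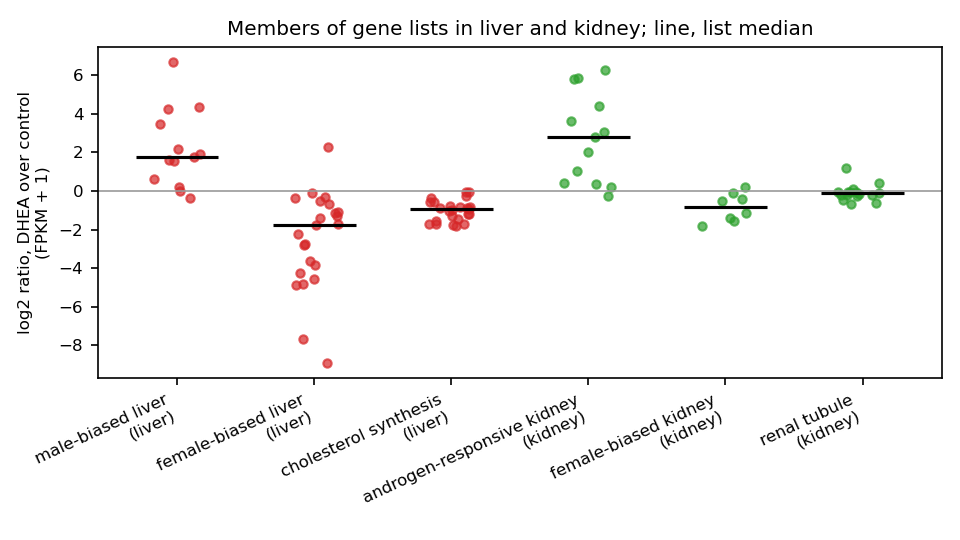
Log2 ratios (DHEA over control, FPKM + 1) of the measured members of 3 lists in liver (red) and 3 lists in kidney (green), 1 point per gene, with the list median as a line. The medians are 1.77 for male-biased and -1.77 for female-biased liver genes, and 2.79 for androgen-responsive and -0.13 for renal tubule genes in kidney.

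In the spleen, erythroid and neutrophil transcripts were higher in the DHEA library. Alas2, the first enzyme of haem synthesis in red cell precursors, was at 44.7 FPKM in control and 539 in DHEA (12.1-fold, 11.5 to 12.7), and Slc4a1, the anion exchanger of red cells, at 63.3 and 578 FPKM (9.13-fold, 8.88 to 9.40). S100a8, an abundant neutrophil protein, was at 41.5 and 392 FPKM (9.45-fold, 8.60 to 10.4), and Retnlg, also typical of neutrophils, at 3.27 and 83.1 FPKM. Erythroid markers had 16 of 18 members 2-fold higher and 0 lower (median 2.33), neutrophil markers 17 of 18 higher and 0 lower (median 1.99), macrophage markers 9 of 16 higher and 0 lower (median 1.01), and cell cycle genes 10 of 29 higher and 0 lower (median 0.87), all apart. B cell markers were not apart (median -0.32, percentile 5.39), and T and NK cell markers were, with 1 of 17 lower, 2 higher and a median of -0.54. Exocrine pancreas genes were higher in 16 of 16 cases (median 2.33, and 3.71 with members at 0 reads at their bound). Ctrb1, a pancreatic chymotrypsinogen, was at least 89.6-fold higher (0 reads against 17.99 FPKM), and Try4, a trypsinogen, was at least 46.8-fold higher. Whether these pancreatic transcripts came from the spleen itself or from other tissue in the sampled piece was not tested. Mitochondrially encoded genes had 12 of 13 members lower and 0 higher (median -1.65), with COX3, ATP6, CYTB (2645 against 737 FPKM) and ND1 among the 5 largest negative ratios beside Ly6k. Ribosomal protein genes were apart on the lower side with all 40 members between the limits (median -0.45).

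In the thymus, transcripts of fat cells were higher in the DHEA library. Cfd, which encodes adipsin, was at 28.3 FPKM in control and 228 in DHEA (8.05-fold, 7.34 to 8.85), and Ucp1, the uncoupling protein of brown fat, at 26.5 and 110 FPKM (4.15-fold, 3.85 to 4.48). Pth, the parathyroid hormone gene, was at 1.51 and 34.4 FPKM (22.7-fold, 14.7 to 37.1), and Chga, a protein of endocrine granules, at 1.22 and 12.9 FPKM. Adipocyte markers had 11 of 15 members 2-fold higher and 0 lower (median 1.59, apart). Whether the fat cell, Pth and Chga transcripts came from the thymus itself or from other tissue in the sampled piece was not tested. Thymocyte markers had all 20 members between the limits (median -0.01, percentile 83.2), and thymic epithelium markers all 15 (median -0.07, percentile 17.7). Cell cycle genes had a median of -0.22 and interferon response genes of -0.22, both apart with 0 members past 2-fold. Cyp2e1 and Hp were also among the 5 largest positive ratios. The largest negative ratios were those of Ly6k (23.3 against 8.01 FPKM), Klk1 and the small RNA genes Mir363, Mir1291 and Mir7656, which rest on 30 reads or fewer.

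In the lung, neutrophil and immediate early transcripts were higher in the DHEA library. S100a9 was at 42.7 FPKM in control and 307 in DHEA (95% interval 6.49-fold to 8.01-fold), and Csf3r, the receptor for granulocyte colony-stimulating factor, at 3.61 and 25.8 FPKM (7.14-fold, 6.23 to 8.21). Fos was at 16.6 and 163 FPKM (9.83-fold, 9.10 to 10.6) and Egr1 at 11.8 and 76.5 FPKM. Neutrophil markers had 8 of 9 members 2-fold higher and 0 lower (median 2.26), and immediate early genes 10 of 22 higher and 0 lower (median 0.70). Airway epithelium markers had 1 of 14 members lower and 0 higher (median -0.67), with Scgb3a2, a secretory protein of club cells, at 1340 and 656 FPKM. Mitochondrially encoded genes were lower in 10 of 13 cases (median -1.24), and ribosomal protein genes (median -0.46) and nuclear genes of oxidative phosphorylation (median -0.39) were apart on the lower side with 0 members past 2-fold. Alveolar epithelium markers were not apart (median 0.02, percentile 88.1). The largest ratios also included S100a8 and Mir143 (2 reads in control and 16 in DHEA) on the higher side. On the lower side they included Ces1g, a carboxylesterase (20.04 against 1.715 FPKM), Ces1f, Cyp2a5, ND4L and Snord138 (12 reads in control and 1 in DHEA).

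In the heart, atrial transcripts were higher in the DHEA library. Myl7, the atrial regulatory light chain of myosin, was at 55.1 FPKM in control and 977 in DHEA (17.7-fold, 16.3 to 19.3), and Sln, the atrial calcium pump regulator sarcolipin, at 6.70 and 104 FPKM (15.5-fold, 13.2 to 18.4). Nppa, the atrial natriuretic peptide gene, was at 275 and 2226 FPKM (8.09-fold, 7.83 to 8.36). Atrial cardiomyocyte markers had 6 of 7 members 2-fold higher and 0 lower (median 3.01, apart), and ventricular markers had all 14 members between the limits (median 0.09, percentile 29.7). Genes of class II antigen presentation had 4 of 6 members lower and 0 higher (median -1.40), with H2-Eb1 at 43.3 and 13.05 FPKM. Macrophage markers were also apart on the lower side, with all 12 members between the limits (median -0.40), as were microglia markers (median -0.60). The cardiac stress list was apart on the higher side with 3 of 13 members higher and 0 lower (median 0.24), namely Nppa, Nppb and Atf3. Mitochondrially encoded genes had 5 of 13 members lower and 0 higher (median -0.77). Mybphl and Myl4 completed the 5 largest positive ratios. Pgc, a pepsinogen gene (14.4 FPKM against 0 reads, at least 103-fold lower), Alb, ATP6, ND4L and H2-Q6 had the largest negative ones.

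In the intestine, B cell and pancreatic transcripts were higher and mucosal secretory transcripts lower in the DHEA library. Cd79a, part of the B cell receptor, was at 3.94 FPKM in control and 203 in DHEA (51.5-fold, 41.6 to 64.5), and Cd79b, its partner chain, at 2.24 and 109 FPKM (48.7-fold, 36.6 to 66.2). Cxcl13, a chemokine that attracts B cells, was at 0.814 and 88.8 FPKM (109-fold, 64.8 to 200.1). Tff2, a trefoil peptide of gastric and duodenal glands, was at 6617 and 1.91 FPKM (3463-fold lower, 2099 to 6187), and Gkn3, a gastrokine, at 2171 and 2.52 FPKM. B cell markers had 13 of 14 members 2-fold higher and 0 lower (median 4.11), cell cycle genes 26 of 29 higher and 0 lower (median 1.91), and ribosomal protein genes 24 of 40 higher and 0 lower (median 1.07), all apart. Exocrine pancreas genes had 16 of 17 members higher and 1 lower (median 3.97), with Ctrb1 at 1.14 and 109 FPKM. Whether the B cell and pancreatic transcripts reflect other tissue in the sampled piece was not tested. Goblet and Paneth cell markers had 14 of 18 members lower and 0 higher (median -1.47), such as Agr2, which folds mucins (294 against 25.5 FPKM). Interferon response genes had 19 of 28 members lower and 1 higher (median -1.13), with Isg15 at 348 and 107 FPKM. Enterocyte markers had 2 of 18 members lower and 0 higher (median -0.46), and intestinal stem cell markers were not apart (median 0.07, percentile 28.6). Fcmr and Ighg2b on the higher side, and Pgc, A4gnt (at least 305-fold lower) and Wfdc18 on the lower side, were also among the 5 largest ratios.

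In the brain, transcripts of the cerebellum were lower and transcripts of forebrain neurons higher in the DHEA library. Gabra6, a receptor subunit of cerebellar granule cells, had 5620 reads in control and 0 in DHEA, at least 1491-fold lower, and Cbln3, a secreted protein of the same cells, was at 258 and 0.0988 FPKM (2615-fold lower, 1327 to 6057). Nrgn, a postsynaptic protein of forebrain neurons, was at 34.3 and 797 FPKM (23.2-fold higher, 21.8 to 24.7), and Neurod6 at 3.07 and 73.7 FPKM (24.0-fold, 20.2 to 28.7). Choroid plexus markers were lower in 12 of 12 cases (median -1.83), with Ttr, the carrier of thyroxine, at 1215 and 209.9 FPKM. Oligodendrocyte markers had 5 of 16 members lower (median -0.84), with Mbp at 650.4 and 308 FPKM, and astrocyte markers 5 of 12 lower (median -0.68), with S100b at 321 and 60.1 FPKM, and 0 members of either list were 2-fold higher. Neuron markers had 3 of 16 members higher and 2 lower (median -0.27, apart, while the list mean of 0.0140 has the opposite sign), and Camk2a, a kinase of excitatory forebrain neurons, was at 55.2 and 531 FPKM. Fezf2, Crym and Miat were the other genes of the 5 largest positive ratios, and Car8, Ppp1r17 and Pcp2, the last a Purkinje cell gene, those of the negative ones.

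**Figure D4:**
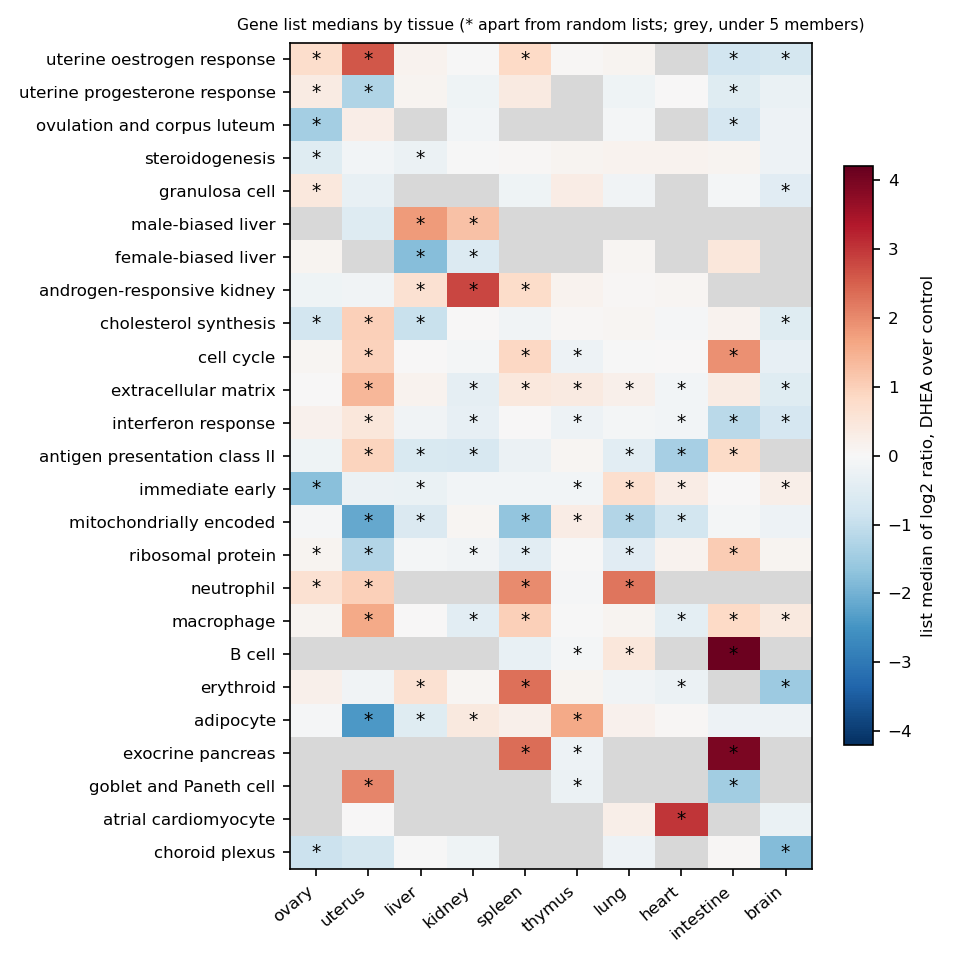
Median log2 ratio (DHEA over control) of 25 gene lists in 10 tissues, with red for higher and blue for lower in the DHEA library, a star for a median apart from random lists and grey for lists with under 5 measured members. The oestrogen response list has its highest median in uterus (2.62) and the male-biased liver list in liver (1.77).

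Across the 10 tissues, 0 genes rose and 0 fell under limma at an adjusted p under 0.05, of 14833 tested, with 1104 genes at an unadjusted p under 0.05. An exact sign-flip test per gene had 1280 genes at an unadjusted p under 0.05, but its smallest possible p of 0.00195 leaves little room for a call after adjustment. Limma-voom on the recovered reads, added after seeing the data, called 9 higher and 6 lower. The smallest p-values, none of which passed, belonged to Nostrin, Sertad1 and Mir5119, each with a limma adjusted p of 0.188. Nostrin, a regulator of nitric oxide synthase traffic, was at log2 -0.54 (SE 0.08, lower in 10 of 10 tissues). Sertad1 was at -0.53 (SE 0.08, lower in 10 of 10) and Mir5119 at 1.22 (SE 0.19, higher in 9 of 10). Mir5119 is a small RNA gene with a mean of 2.91 FPKM over the libraries, and its reads are not given here. Nab2 (-0.51), Rbm12b2 (-0.44) and H2-Q4 (-0.58) were lower in 9 of 10 tissues each, and Herc2 (0.40), Srsf5 (0.41), Dagla (0.29) and Msrb3 (0.34) were higher in at least 9 of 10, with a limma adjusted p of 0.659. The same direction in all 10 tissues was found for 60 genes (40 higher, 20 lower), 0.405% of those tested. The share would be 0.195% if both directions were equally likely and the tissues independent. Tissues of the same mouse are not independent, and the spread of this share was not examined, so no excess is shown. Leaving out the intestine libraries gave 1 call by limma, Fgfbp3, named outside the rule after its values were seen (log2 -0.71, adjusted p = 0.00689, against -0.59 and 0.659 with all tissues). Among 25 gene lists with a median in every tissue, 0 passed the exact sign-flip test after adjustment, and the smallest p, 0.0352 by the exact test (adjusted 0.798), was that of the mitochondrially encoded genes (mean of medians -0.64, lower in 8 of 10 tissues).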

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

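Of the tests in this part, those on library scaling, the proximal tubule, the uterine epithelium, the oestrous stage, the atrium and the ventricular stress genes were chosen only after the result was seen. The genes for the tests on the sampled part of brain and gut and on stomach tissue were picked after the 12 largest ratios of each tissue had been seen and before their own values. Some of them also belong to the fixed lists, such as Pvalb and Cux2 in brain and Lct, Fabp6, Slc51a and Slc51b in intestine. These were not fully held out, since the bile acid list median in intestine (-0.59) was the value of Slc51a. The value given for the stomach test was changed, after its result was seen, from the median of the measured genes, which is -2.32 on 1 gene and alone would go with stomach tissue, to the number of genes present. The test on ventricular stress genes was also rewritten after its values were seen. It first used Myh7, Acta1, Ankrd1 and Xirp2 (median 0.17), which went against a stress response. A second form, which added the call of the whole list, could not decide. The form given here uses the median of the whole list.

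Lists that stood apart with a median of size at least 1 on the log2 scale and opposite signs in a pair of tissues were singled out, and 4 lists met this. Adipocyte markers were at -2.41 in uterus and 1.59 in thymus, erythroid markers at 2.33 in spleen and -1.53 in brain, goblet and Paneth cell markers at 2.07 in uterus and -1.47 in intestine, and ribosomal protein genes at -1.24 in uterus and 1.07 in intestine. These differences between tissues were not tested, since each tissue has 1 pair of libraries.

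The sex-biased transcripts of liver and kidney went in the male direction in the DHEA libraries. A male mouse among the samples is argued against by the Y-linked genes Ddx3y and Kdm5d, the 2 of 4 looked for that are in the table, whose sum was at most 0.0116 FPKM in any of the 20 libraries, while Xist was at 1.39 to 36.7 FPKM. Scaling moves all genes of a library alike, and is argued against by medians 3.55 apart on the log2 scale between male-biased and female-biased genes in liver and 3.62 between androgen-responsive and female-biased genes in kidney. A larger share of proximal tubule as a whole is argued against as the source of the 2-fold rises in kidney. It would raise the proximal genes of the renal tubule list, such as Lrp2 and Slc34a1, together with the androgen-responsive list (median 2.79). Of the 16 measured renal tubule members, 1 was 2-fold higher and 0 were 2-fold lower. In all, 3 were higher and 13 lower (median -0.13, quartiles -0.23 and -0.05). That list also holds genes of other segments, such as Umod and Aqp2, and its proximal genes were not read separately. A larger share of a part of the proximal tubule therefore stays open. Another candidate explanation that remains is a response to androgens formed from DHEA. It is a hypothesis found and examined on the same libraries, which hold no measure of androgens. It was not separable here from differences between single mice.

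The oestrogen-response transcripts of the uterus were far higher in the DHEA library. Neutrophils as the source of Ltf are argued against by S100a8 and S100a9. They reached at most 0.00537% of the level that the Ltf value and the ratio in spleen would require. S100a9 was at 5.26 and 8.70 FPKM, and Ngp and Camp were at 0 in the DHEA uterus. No such level was computed for Lcn2. A larger share of epithelium is argued against by a median of 0.24 for Krt8, Krt18, Krt19, Epcam and Cdh1. The oestrous stage of the mice may give the same picture and cannot be told apart from DHEA, because the design holds 1 control uterus library and its stage is not given in the sources used here. The same limit holds for the ovary pair. Fat and ciliated cell transcripts were lower in the same library, so a different mix of tissue also stays open for part of the list.

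The brain, intestine and heart pairs may differ in the part of the organ that was sampled. In brain, 14 of 14 cerebellar genes picked for this test, of which Pvalb also belongs to a fixed list, were 2-fold lower (median -2.76). Of the cortical and hippocampal genes, 7 of 14 were 2-fold higher (median 1.04, lower quartile 0.38), which is less uniform and close to the bound of 1 set for it. In heart, atrial genes outside the natriuretic peptides had a median of 2.92 and ventricular genes of 0.09. The cardiac stress list had a median of 0.24 (upper quartile 0.52) and stood apart on the higher side. Its shift was thus smaller than that of the atrial genes. The bounds of the stress test were set with these values known, so it cannot decide on a ventricular stress response, which stays open. In intestine, stomach tissue in the control piece is argued against by 1 of 14 stomach genes at 1 FPKM or more (Ctse). Duodenal genes had a median of -1.46, with 5 of 9 measured members 2-fold lower and 0 higher. The 5 measured ileal genes had a median of -0.36, and Fabp6, Slc10a2, Fgf15 and Osr2 were under 1 FPKM in both libraries. The test asked for a rise of ileal genes, so it could not decide on a shift between other stretches. A different stretch of gut therefore stays open and cannot be told apart from other causes. An effect of DHEA in these organs stays open and was not separable from the sampled part.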

How the results depend on the processing

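The fits by limma-voom and without brain, intestine and heart were chosen after seeing the data, and the other alternatives before. Pseudocount 0.1, centring on the tissue median and rescaling kept each of the 20 counts of 2-fold genes within 1.5 times its value. Filters and thresholds moved the counts by their construction, since more or fewer genes enter. With a pair mean of at least 1 FPKM, the counts that moved were 278 higher in ovary, 996 higher and 1282 lower in uterus, 123 and 194 in liver, 125 and 74 in kidney, 718 and 140 in spleen, 195 and 37 in thymus, 175 and 106 in lung, 55 and 49 in heart, 1354 higher in intestine and 734 lower in brain. With no filter they were 323 higher and 374 lower in ovary, 1076 and 1423 in uterus, 140 and 237 in liver, 160 and 111 in kidney, 787 and 161 in spleen, 239 and 63 in thymus, 209 and 123 in lung, 73 and 68 in heart, 1470 and 315 in intestine, and 661 and 804 in brain. At 4-fold they were 21 higher and 72 lower in ovary, 231 and 171 in uterus, 17 and 16 in liver, 27 and 6 in kidney, 96 and 7 in spleen, 20 and 2 in thymus, 14 and 6 in lung, 7 and 4 in heart, 202 and 37 in intestine, and 103 and 103 in brain. The authors' deposited table, which holds fewer genes and 1 constant per tissue, gave 498 lower in uterus, 33 higher in kidney, 42 higher and 3 lower in thymus, 114 and 17 in lung, 81 lower in intestine and 207 higher in brain.

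Of 213 combinations of list and tissue that stood apart, 205 stayed so with pseudocount 0.1, 165 by the list mean and 147 at 5 FPKM or more, where 49 had too few members. Centring cannot change these calls, since it moves a list and its random lists alike. At 5 FPKM, the acute phase list in uterus turned to -0.73 and the glucocorticoid response list in liver to 0.0102. By the list mean, the sign turned for CAR and PXR targets in kidney (-0.32) and thymus (0.0108), fatty acid synthesis in kidney (-0.16), alveolar epithelium (0.12) and acute phase genes (0.17) in thymus, endothelium in heart (0.0342) and neurons in brain (0.0140). The cause was not tested.

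Across tissues, limma called 0 genes under each alternative fixed beforehand except without intestine, which gave 0 higher and 1 lower. Leaving out each tissue in turn gave 0 to 0 higher and 0 to 1 lower, and 728 to 1204 genes at an unadjusted p under 0.05. The fit without brain, intestine and heart called 0 genes (1331 at an unadjusted p under 0.05). Limma-voom called 9 higher and 6 lower, and Nab2 was the only 1 of the 10 genes named across tissues to pass in it (adjusted p = 0.0354). S100a9 and Ucp1 (adjusted p = 0.0451 each) and S100b (adjusted p = 0.0354), which are named within tissues, passed in it as well. No list passed in any of the alternatives run. The tissue block pairs the control and DHEA libraries of a tissue, and without it 0 genes were called and 4 had an unadjusted p under 0.05. Of 100 swaps of the labels within tissues, 100 gave at least as many calls as the real 0, and the highest of the others was 0. With 0 real calls this outcome is fixed by construction, so the swaps decide nothing about chance. A table with several columns per sample was not found, so that alternative was not run. The depth limits small RNA genes, several of which rest on 30 reads or fewer.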

Other observations

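The test of the class I genes and the limma-voom fit were chosen only after the result was seen.

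S100a9, a neutrophil calcium-binding protein, was higher in the DHEA library in 10 of 10 tissues, with a mean log2 difference of 0.99 that did not pass limma (adjusted p = 0.659) and passed limma-voom on the recovered reads (adjusted p = 0.0451). The neutrophil list, measured in 5 tissues, was apart on the higher side in ovary (median 0.64), spleen and lung, and not in thymus (-0.04, with 5 members higher and 5 lower). In uterus the list was also apart on the higher side (0.996, 7 of 8 members higher) and holds Ltf and Lcn2. Outside these, S100a9 was at 5.26 and 8.70 FPKM and Csf3r at 0.536 and 2.75, while S100a8 was at 4.04 and 1.90 and Ngp at 1.73 and 0. Mitochondrially encoded genes took 2.47% of reads in control and 0.838% in DHEA in spleen, 3.13% and 1.42% in lung, and 16.1% and 10.7% in heart. The shares went the other way in kidney (4.99% and 5.46%) and in thymus (0.661% and 0.896%), where the list was apart on the higher side (median 0.33). In the uterus, interferon response genes had 8 of 28 members 2-fold higher and 2 lower (median 0.47), and Oas3, an antiviral sensor, was at 0.961 and 9.80 FPKM. Circadian clock genes had 8 of 18 members lower and 1 higher in uterus (median -0.72), with Dbp at 9.44 and 1.35 FPKM.

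In the spleen, genes of the oxidative stress response had 5 of 19 members 2-fold higher and 1 lower (median 0.58), among them Hmox1, which breaks down haem (128 against 354 FPKM). In the kidney, class II antigen presentation genes had 6 of 6 members between the limits and a median of -0.67, apart from random lists, with Cd74 at 150.1 and 87.0 FPKM. Macrophage markers, with all 10 members between the limits (median -0.44), and microglia markers (median -0.33) were apart on the lower side in the same pair. In the liver, unfolded protein response genes had 3 of 15 members higher and 1 lower (median 0.69), with the chaperone Hyou1 at 19.3 and 48.0 FPKM.

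H2-Q4, a class I gene, was among the genes with the smallest p across tissues, and lower expression of the class I pathway as a whole was examined as a hypothesis. Across 10 other class I pathway genes, such as Tap1 and Psmb8, the mean of tissue medians was -0.20 (SD 0.18 over tissues, exact two-sided sign-flip permutation p = 0.0117), lower in 8 of 10 tissues and higher in ovary (0.14) and uterus (0.05). This may reflect a small difference shared by organs of the same mice, and the p-value is not adjusted for the other lists that could have been chosen. The 10 genes were tested in the same libraries in which H2-Q4 stood out, and may vary together with it. The test is therefore no independent support for the hypothesis. The interferon response list, which shares 0 genes with these, was lower in 7 of 10 tissues (exact sign-flip p = 0.176). It was higher in ovary (0.18), uterus (0.47) and spleen (0.004). The shift is therefore not shown to be particular to the class I pathway.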
